A study of Mus musculus with 58 samples.

How the data were processed

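The series holds 58 Affymetrix arrays, labelled by the GeneChip HT 3′ IVT PLUS procedure, of the prefrontal cortex and hippocampus of transgenic and wild-type mice of both sexes at 8 months. Per the labels' protocols, brains were dissected on dry ice and RNA was purified on columns. The deposited values are log2 expression values, 1 per probe set, which the authors computed by RMA (background correction, quantile normalization and median polish) in R 3.2.2, per the submitters' processing notes. The chip definition file is not given in the sources used here. There are 17856 probe sets with values from 2.28 to 13.6, and the array medians lie between 4.73 and 4.85, the 25th percentiles between 3.26 and 3.38. No detection calls were used, so dim genes were neither removed nor marked. Each probe set maps to at most 1 gene: 17216 carry a gene symbol and were analysed as genes, and 640 without a symbol were analysed apart.

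The values were used as deposited, without further scaling. Tests were run in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and figures were drawn in Python 3.11.15. For each region, group means of its 4 groups were fitted with lmFit and eBayes (default prior), and contrasts gave TG against WT in each sex, the sex difference of that effect, and WT females against WT males. The region difference of the TG effect was fitted over all 8 groups. Tests were two-sided, with Benjamini-Hochberg adjustment over 17216 genes at 0.05 and intervals at 95%. Fold changes are log2 values. Counts at 1.5-fold use the estimate.

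Gene lists, named genes, tests and the alternatives that the design lists were chosen before the data were examined. Of 30 lists with 478 members, 423 were measured, and 29 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01. The adjustment ran over 116 tests for TG against WT and over 58 for each of the sex differences, WT females against males and the region differences. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Camera's preset passed 67, 13, 8 and 25 tests of these families, of which 37, 0, 1 and 0 also passed with an estimated correlation. Named genes are App and Thy1, the 10 largest rises and 10 largest falls past the threshold in each TG comparison, up to 4 members of smallest p from each list, and for the other contrasts the 10 genes of smallest p past the threshold, or the 3 of smallest p if none passed. Genes named outside this rule are list members given as examples after their values were seen.

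Arrays of a mouse share its number across regions, per the labels' protocols, which describe both regions as taken from each brain, so the numbers pair 28 mice. Deviations from the group means of a mouse's 2 arrays had correlations from -0.033 to 0.363, median 0.111, over 0.1 in 15 of 28 mice, and 15 of 28 mice matched themselves best in their group. The replicate block with the mouse as a fixed term gave 726 and 406 region differences in males and females. The fits were tested on simulated data with each gene's residual spread pooled over all groups. In these, 50 genes drawn at random were raised or lowered by each of several amounts. A log2 change of 0.4 was found for 72% to 84% of genes in the TG comparisons and a change of 1 for at least 98%.

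Alternatives were equal array medians, quantile normalization over the arrays of a fit, the brighter part of the genes, every probe set, a trended robust prior, array weights, fits over all groups or over the groups compared only, the mouse as a fixed or random block, a threshold of 0.01 for overlaps, and leaving out each array. After the data were seen, fits without the hippocampus arrays of mice 4 and 7, without the frontal cortex array of mouse 51, with the mean of the choroid plexus list as a covariate, and list tests under the block were added. Other splits of the samples were drawn 100 at a time, the real one included.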

Results

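RNA was measured in the prefrontal cortex (named frontal cortex in the labels) and the hippocampus of 30 mice aged 8 months, on 58 Affymetrix arrays. The transgenic mice (TG) carry mutant human amyloid precursor protein under the neuronal Thy1 promoter and deposit amyloid in the brain, and the wild-type mice (WT) are their controls. The 8 groups hold 8 male WT and 8 male TG arrays in each region, 6 female WT and 6 female TG arrays of the frontal cortex, and 7 female WT and 7 female TG arrays of the hippocampus. Of the 30 mice, 28 gave an array of each region. Array medians lay between 4.73 and 4.85 on the log2 scale, and 17216 genes with a name were tested. The number of arrays limits the precision of every value, and folds of genes near the low end of the scale are understated. The arrays measured dissected tissue, so a change in the number of cells of a type cannot be told apart from a change within them. Errors beside log2 fold changes are standard errors from limma, and those beside group means are SD. The male and female mice carry separate ranges of numbers, so a difference between the sexes cannot be told apart from a difference between batches of animals, if there were any.

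What the transgenes changed in the male frontal cortex was asked first, with 8 TG and 8 WT arrays. Thy1, whose promoter drives the transgenes, rose by 1.22 log2 units (SE 0.09) from a WT mean of 10.91 (SD 0.28). Whether this signal came from the mouse gene or from transgene sequence was not tested, here or in the other groups. Mouse App fell by 0.18 (SE 0.05, adjusted p = 0.00439). The rise was steepest for microglial genes that mark cells around plaques. Cst7, an inhibitor of lysosomal cathepsins, rose by 6.72 log2 units (SE 0.18) from 3.26 (SD 0.18) to 9.98 (SD 0.27). It was followed by the beta-glucan receptor Clec7a, up by 5.01 (SE 0.16), and lysozyme Lyz2, up by 4.06 (SE 0.26). Trem2, a lipid-sensing receptor in which variants raise the risk of Alzheimer's disease, rose by 3.38 (SE 0.17), and its signalling partner Tyrobp by 3.25 (SE 0.13). Gfap, the filament protein of reactive astrocytes, rose by 3.75 (SE 0.19). Cd52, Cd68, Ccl6 and Ccl3 completed the 10 largest rises, between 3.22 and 3.68. The 10 largest falls were smaller, between -0.87 and -0.75. They were led by the prohormone convertase Pcsk1 (-0.87, SE 0.16), the activity-regulated gene Arc (-0.83, SE 0.27), the somatostatin receptor Sstr2 (-0.82, SE 0.18), the phosphatase Dusp1 (-0.80, SE 0.15) and the neurotrophin Bdnf (-0.80, SE 0.14). The others were Cbln4, Hspa1b, Dyrk3, Kcnab1 and Grm8.

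Gene groups in the male frontal cortex moved as follows. Of 29 measured genes of plaque-associated microglia, 26 rose and 3 did not pass (26 rose when adjusted over the list alone), with a median change of 1.40. Genes of homeostatic microglia, which mark the resting state, also rose (14 of 15, median 1.51, and 15 adjusted over the list alone), among them Csf1r (1.63, SE 0.09) and Gpr34 (2.44, SE 0.13). Complement and Fc receptor genes rose in 12 of 13 (13 adjusted over the list alone), with C1qb at 2.48 (SE 0.14). So did 14 of 15 interferon response genes (15 adjusted over the list alone) and 9 of 12 antigen presentation genes (11 adjusted over the list alone), such as B2m at 1.94 (SE 0.10). Lysosomal genes rose in 15 of 21 (16 up and 1 down adjusted over the list alone), led by Ctsz (2.62, SE 0.13) and Ctss (2.13, SE 0.11). Astrocytes took part: 11 of 14 astrocyte markers rose (12 adjusted over the list alone), with the water channel Aqp4 at 1.02 (SE 0.13), and 10 of 21 genes of reactive astrocytes (12 adjusted over the list alone). Among 17 genes at loci of Alzheimer's disease risk, 10 rose and 2 fell (10 and 3 adjusted over the list alone). The phospholipase Plcg2 rose by 1.31 (SE 0.14), and the sorting receptor Sorl1 fell by 0.30 on the log2 scale. Each of these 9 groups passed camera, and each kept its call with an estimated correlation, the highest adjusted p being 0.0486 for astrocyte markers.

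Neuronal groups of the male frontal cortex went the other way. Interneuron genes fell in 6 of 17 (7 adjusted over the list alone), including the neuropeptides Sst (-0.49, SE 0.09), Tac1 (-0.53, SE 0.11) and Cck (-0.33, SE 0.07). The group's call was kept (adjusted p = 0.0378 with an estimated correlation). Immediate early genes, which neuronal activity induces, fell in 17 of 23 (19 adjusted over the list alone) with a median of -0.47. The group's call was lost (adjusted p = 0.0665 with an estimated correlation). Of 15 genes of excitatory neurons and synapses, 7 fell, 1 rose and 7 did not pass (8 and 1 adjusted over the list alone). The vesicular glutamate transporter Slc17a7 was at -0.29 (SE 0.07) and the kinase Camk2a at 0.20 (SE 0.06), and the group's call was also lost (adjusted p = 0.293 with an estimated correlation). Heat shock and ER stress genes fell in 11 of 22 and rose in 2 (the same numbers adjusted over the list alone). The chaperone genes Dnajb1 and Hsph1 were at -0.57 (SE 0.10) and -0.44 (SE 0.08), again without a call that held (adjusted p = 0.297 with an estimated correlation). In all, 3534 genes changed, 1515 higher and 2019 lower in TG, and 370 of the rises and 44 of the falls reached 1.5-fold. With the array medians made equal the split was 1182 higher and 3403 lower, so the balance of small rises and falls depends on the scaling. Arc lost its call without the TG array of mouse 40 (adjusted p = 0.0574).

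In the female frontal cortex, with 6 TG and 6 WT arrays, Thy1 rose by 1.17 log2 units (SE 0.10) from 10.95 (SD 0.04), and App, at -0.15 (SE 0.05), did not pass (adjusted p = 0.0543). The same 10 genes as in males had the largest rises, with Cst7 at 6.76 (SE 0.21), Clec7a at 5.33 (SE 0.19) and Gfap at 4.14 (SE 0.21). Lower came Lyz2 at 4.09 (SE 0.30), Cd52 at 4.08 (SE 0.21) and Trem2 at 3.52 (SE 0.19). The largest falls were Adcyap1, the neuropeptide PACAP, at -1.13 (SE 0.13), the Wnt antagonist Frzb at -1.05 (SE 0.28), and Tafa1 at -0.95 (SE 0.15). They were followed by Rnd1 at -0.83 (SE 0.17) and Neurod6, a transcription factor of cortical pyramidal neurons, at -0.82 (SE 0.19). Plcxd3, Trhde, Ankrd34b, Ankrd63 and Ramp3 completed the 10, between -0.81 and -0.76.

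By group, 26 of 29 genes of plaque-associated microglia rose in the female frontal cortex (26 adjusted over the list alone), with a median of 1.78. All 15 genes of homeostatic microglia rose (15 adjusted over the list alone), as did 12 of 13 complement and Fc receptor genes (13 adjusted over the list alone). Rises also took in 11 of 12 antigen presentation genes (11 adjusted over the list alone) and 15 of 15 interferon response genes (15 adjusted over the list alone), such as H2-D1 at 2.04 (SE 0.17) and Lgals3bp at 3.30 (SE 0.19). Lysosomal genes rose in 15 of 21 (16 adjusted over the list alone), and astrocyte markers in 13 of 14 (14 adjusted over the list alone). Genes of reactive astrocytes rose in 13 of 21 (15 adjusted over the list alone), such as Serpina3n at 2.91 (SE 0.25). At the risk loci 11 of 17 rose and 3 fell (12 and 3 adjusted over the list alone). The lipid carrier Clu rose by 0.64 (SE 0.08). Interneuron genes fell in 9 of 17 (9 adjusted over the list alone), with Sst at -0.63 (SE 0.10) and Cort at -0.73 (SE 0.13). These 10 groups passed camera and kept their call with an estimated correlation, the highest adjusted p being 0.0432 for astrocyte markers. Excitatory neuron and synapse genes fell in 9 of 15 and rose in 1 (the same numbers adjusted over the list alone), with synaptophysin, Syp, at -0.41 (SE 0.06). Immediate early genes fell in 8 of 23 (9 adjusted over the list alone). Both of those calls were lost (adjusted p = 0.0525 and adjusted p = 0.219 with an estimated correlation). Among genes of APP processing, the protease Adam17 rose by 0.73 (SE 0.09) and the beta-secretase Bace1 fell by 0.26 on the log2 scale (SE 0.07), while the group did not pass (adjusted p = 0.444). In all, 3257 genes changed, 1507 higher and 1750 lower, and 495 rises and 65 falls reached 1.5-fold. With equal array medians the split was 1190 higher and 2804 lower.

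**Figure D1:**
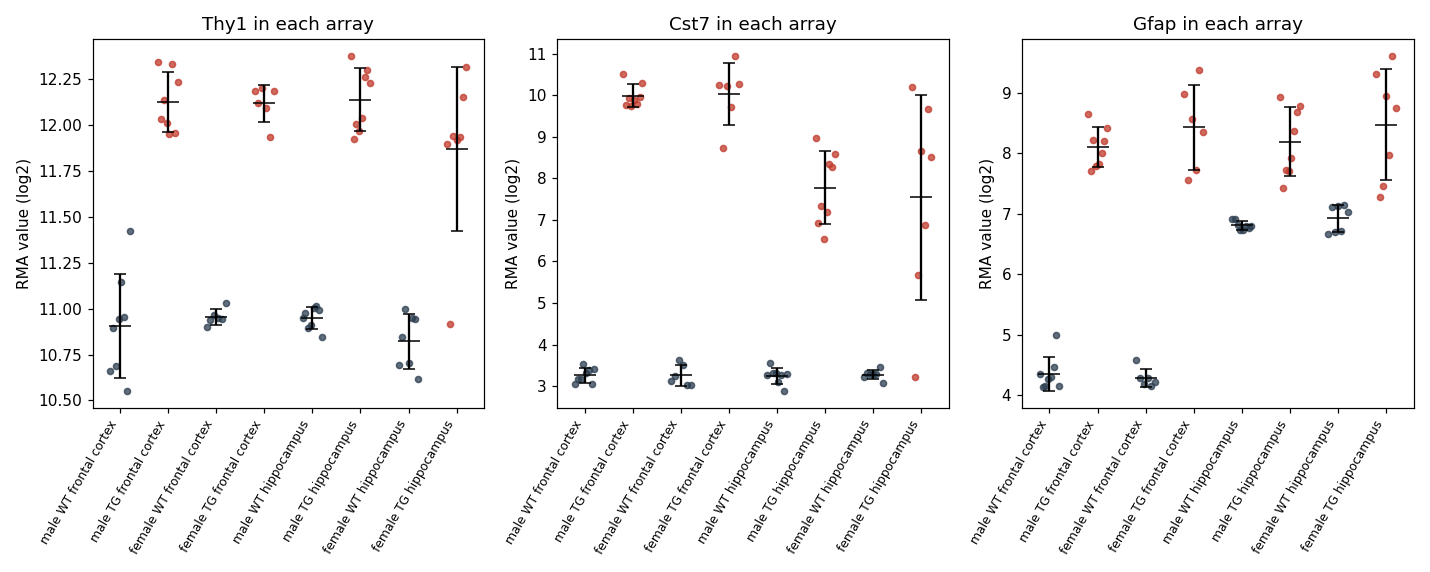
RMA values (log2) of Thy1, Cst7 and Gfap in each of the 58 arrays, with 1 point per array, the group mean and SD as bars, WT in dark grey and TG in red. Among the female TG hippocampus arrays, 1 point lies at 10.92 for Thy1 and 3.21 for Cst7, within the range of the WT arrays.

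In the male hippocampus, with 8 TG and 8 WT arrays, Thy1 rose by 1.19 log2 units (SE 0.12) and App was at -0.02 (SE 0.04, adjusted p = 0.907). The microglial genes led again, at lower values. Cst7 rose by 4.52 (SE 0.59) from 3.25 (SD 0.19) to 7.77 (SD 0.88). Clec7a rose by 3.35 (SE 0.49), Lyz2 by 2.46 (SE 0.37), Tyrobp by 2.03 (SE 0.31) and Trem2 by 1.95 (SE 0.34). Cd52, Cd68, Mpeg1, Ccl6 and Ly86 completed the 10 largest rises, between 1.61 and 2.28, and Gfap rose by 1.38 (SE 0.25). Activity-regulated genes made up most of the 10 largest falls, including Dusp1 (-0.68, SE 0.14), Nr4a2 (-0.65, SE 0.14) and Npas4 (-0.63, SE 0.12). Beside them were the heparan sulfate enzyme Hs3st2 (-0.67, SE 0.13), the synaptic adhesion protein Lrrc4c (-0.50, SE 0.09) and the transcription factor Fezf2 (-0.50, SE 0.10). Fos (-1.03, SE 0.27, adjusted p = 0.0497), Arc (-0.90, SE 0.21), Nr4a1 (-0.68, SE 0.17) and Crhbp (-0.53, SE 0.13) passed, but each call was lost without any 1 of several arrays. These were 14 of the 16 for Fos (those of mice 43 and 52 excepted) and 7 for Arc (mice 40, 42, 44, 48, 49, 50 and 53). They were 10 for Nr4a1 (mice 38, 39, 40, 42, 44, 46, 48, 49, 50 and 53) and 11 for Crhbp (mice 38, 39, 40, 44, 45, 46, 47, 49, 50, 51 and 53).

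Genes of plaque-associated microglia rose in 17 of 29 in the male hippocampus (24 adjusted over the list alone), with a median of 0.69, and genes of homeostatic microglia in 8 of 15 (13 adjusted over the list alone). Complement and Fc receptor genes rose in 8 of 13 (13 adjusted over the list alone), with C1qa at 1.29 (SE 0.25), and lysosomal genes in 12 of 21 (13 adjusted over the list alone), with Ctss at 1.20 (SE 0.20). Interferon response genes rose in 4 of 15 (13 adjusted over the list alone), genes of reactive astrocytes in 4 of 21 (11 adjusted over the list alone), and at the risk loci 1 of 17 (5 adjusted over the list alone). Immediate early genes fell in 9 of 23 (17 adjusted over the list alone), with a median of -0.34. All these groups passed camera and kept their calls, the highest adjusted p being 0.0452 for interferon response and that of immediate early genes 0.00857 with an estimated correlation. Antigen presentation rose in 3 of 12 (8 adjusted over the list alone; adjusted p = 0.0525 with an estimated correlation), and no astrocyte marker passed (2 higher adjusted over the list alone). Markers of the choroid plexus, the ventricle tissue that secretes cerebrospinal fluid, had a median of 1.66 with 0 of 15 genes past limma's threshold (13 higher adjusted over the list alone; adjusted p = 0.151 with an estimated correlation). Ttr, which carries thyroid hormone, ranged from 6.92 to 13.56 in WT and from 8.75 to 13.58 in TG arrays, up to the top of the range of values. The mean of the markers was above 6 in 5 of the 8 TG arrays and 1 of the 8 WT arrays, and markers of meninges and fibroblasts moved with them (median 0.44, 0 of 10 past the threshold, 8 higher adjusted over the list alone, adjusted p = 0.0468 with an estimated correlation).

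In all, 224 genes changed in the male hippocampus, 179 higher and 45 lower, 96 of the rises and 7 of the falls by at least 1.5-fold. With equal array medians the split was 137 higher and 108 lower. The count depended on single arrays. It came to 142, 122, 123, 111, 124 and 337 without the WT arrays of mice 38, 47, 48, 49, 51 and 52. It came to 96, 94 and 96 without the TG arrays of mice 40, 50 and 53, and to 431 without the female TG array of mouse 4, which enters through the shared spread. With the mean of the choroid plexus markers as a covariate it came to 60, with array weights to 616 and with the male arrays alone to 518.

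In the female hippocampus, 7 TG and 7 WT arrays were compared, and the array labelled female TG hippocampus mouse 7 lay at the WT level for Thy1 (10.92, against 11.90 to 12.32 in the other TG arrays and a WT mean of 10.82, SD 0.15). Thy1 rose by 1.05 log2 units (SE 0.12) and App was at -0.02 (SE 0.04, adjusted p = 0.897). Cst7 rose by 4.26 (SE 0.63) from 3.28 (SD 0.12) to 7.54 (SD 2.46), and by 4.99 without mouse 7, where Thy1 rose by 1.21. Clec7a rose by 2.98 (SE 0.53), Lyz2 by 2.38 (SE 0.39), Trem2 by 2.01 (SE 0.36) and Gfap by 1.55 (SE 0.27). With Cst7, Clec7a, Lyz2 and Trem2, the genes Cd52, Ccl6, Cd68, Tyrobp, Lgals3bp and Mpeg1 made up the 10 largest rises. Immediate early genes dominated the falls: Arc (-1.06, SE 0.23), Nr4a1 (-0.91, SE 0.18), Egr1 (-0.87, SE 0.17), Junb (-0.76, SE 0.15), Dusp1 (-0.72, SE 0.15), Egr2 (-0.63, SE 0.14) and Egr4 (-0.63, SE 0.10). The retinoic acid-degrading enzyme Cyp26b1 fell by 0.65 on the log2 scale (SE 0.12). Scn4b (-0.79, SE 0.19) and Gkn3 (-0.75, SE 0.20) passed as well, but Scn4b lost its call without the array of mouse 1, 3 or 11 and Gkn3 without that of mouse 1, 2, 5, 6, 7, 9, 10, 11 or 12.

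Of the genes of plaque-associated microglia, 22 of 29 rose in the female hippocampus (28 adjusted over the list alone), with a median of 0.79. So did 9 of 15 of homeostatic microglia (14 adjusted over the list alone) and 10 of 13 complement and Fc receptor genes (12 adjusted over the list alone). The rise was shared by 10 of 21 lysosomal genes (14 adjusted over the list alone), 6 of 15 interferon response genes (12 adjusted over the list alone) and 5 of 21 genes of reactive astrocytes (13 adjusted over the list alone). Sparc, a matrix protein of microglia and vessels, rose by 0.62 (SE 0.08), and the lysosomal mannosidase Man2b1 by 0.82 (SE 0.14). Cholesterol synthesis genes rose in 5 of 14 (10 adjusted over the list alone), with Fdft1, which makes squalene, at 0.37 (SE 0.06) and Sqle at 0.27 (SE 0.06). The mean of this list was also higher in TG elsewhere. It was 7.30 (SD 0.03) in TG against 7.15 (SD 0.05) in WT in the male hippocampus. In the frontal cortex it was 7.50 (SD 0.10) against 7.32 (SD 0.12) in males and 7.60 (SD 0.07) against 7.39 (SD 0.06) in females. Immediate early genes fell in 11 of 23 (21 adjusted over the list alone), with a median of -0.44. These 8 groups passed camera and kept their calls, the highest adjusted p being 0.0432 for interferon response and that of immediate early genes 0.00606 with an estimated correlation. Among calls that were lost were those of antigen presentation (1 of 12 rose, 9 adjusted over the list alone; adjusted p = 0.0752 with an estimated correlation), the risk loci (4 of 17 rose and 1 fell, 9 and 1 adjusted over the list alone; adjusted p = 0.0584 with an estimated correlation) and hippocampal field markers (2 of 13 fell, 3 adjusted over the list alone; adjusted p = 0.0844 with an estimated correlation). The mean of the hippocampal field markers was 5.31 in the TG array of mouse 4 and 6.41 or more in the other TG arrays.

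In all, 425 genes changed in the female hippocampus, 265 higher and 160 lower, 135 of the rises and 10 of the falls by at least 1.5-fold. With equal array medians the split was 218 higher and 234 lower. The count came to 255 and 266 without the WT arrays of mice 1 and 3, to 178 without the TG array of mouse 11 and to 566 without that of mouse 7. With the female arrays alone it came to 22, and of the 58 named genes past the threshold 5 held in every setting (Thy1, Lgals3bp, Cyp26b1, Sparc and Man2b1).

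**Figure D2:**
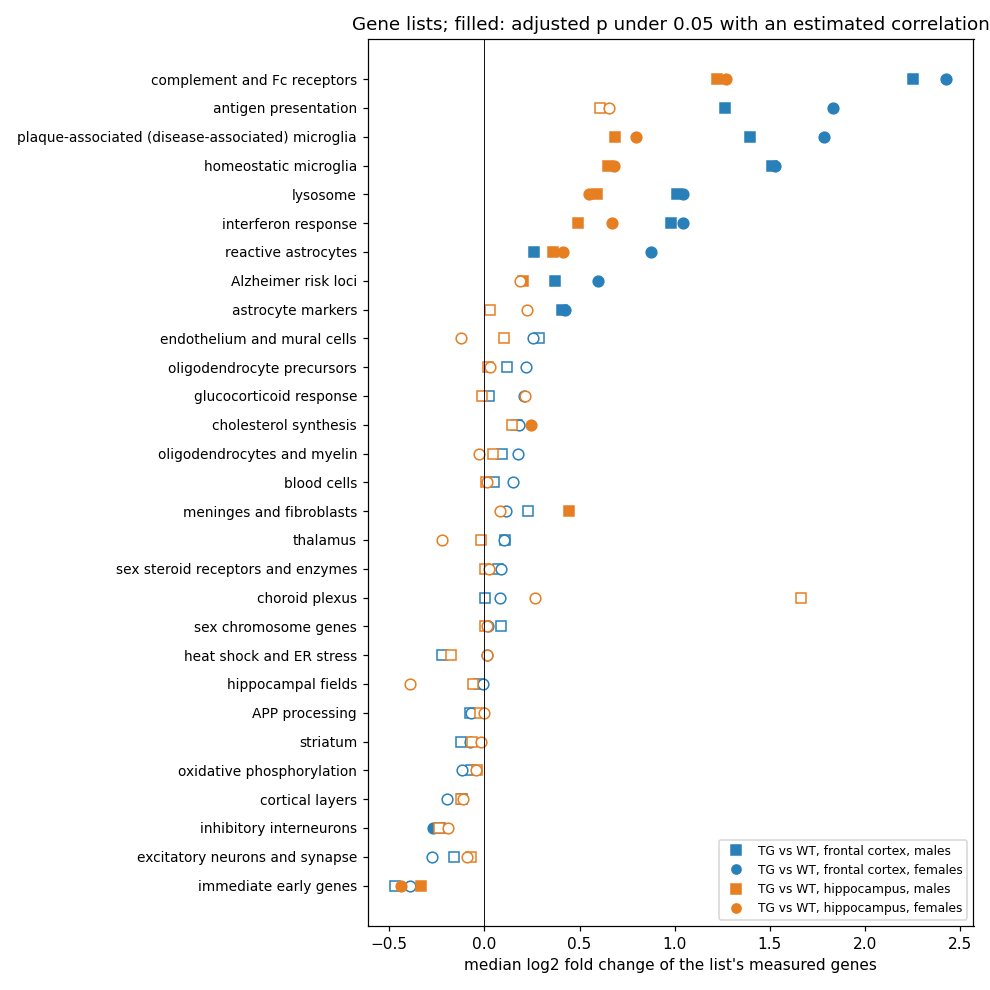
Median log2 fold change of the measured genes of each of 29 gene lists in the 4 TG against WT comparisons, with squares for males, circles for females, blue for frontal cortex and orange for hippocampus; filled symbols mark an adjusted p under 0.05 with an estimated correlation. The plaque-associated microglial list lies at 1.40 and 1.78 in the frontal cortex and at 0.69 and 0.79 in the hippocampus.

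Whether the effect of the transgenes differed between females and males, the question in the title of the series, was tested as the difference of the 2 effects. No gene passed in the frontal cortex, where limma called 0 genes, with 1130 at an unadjusted p under 0.05 and 860.8 due to chance. The smallest p values were those of Zfp109 (0.46, 95% interval 0.25 to 0.66, adjusted p = 0.639), Fras1 (-0.53, interval -0.79 to -0.28) and Pspc1 (-0.47, interval -0.69 to -0.24). In the hippocampus limma also called 0 genes, with 842 at an unadjusted p under 0.05, and Hbegf (0.37, interval 0.19 to 0.54, adjusted p = 0.975), Klf16 and Rpap3 had the smallest p. These values include the array of mouse 7, which lies at the WT level; without it 0 genes passed and 1000 had an unadjusted p under 0.05. The difference for Thy1 was -0.05 (interval -0.33 to 0.22) in the frontal cortex and -0.14 (interval -0.49 to 0.20) in the hippocampus, where it was 0.02 without mouse 7. Of the 4680 genes called in either sex in the frontal cortex, 99.1% had an interval of the sex difference within 1 log2 unit of 0, as did 94.9% of 531 in the hippocampus and 92.6% of 685 there without mouse 7. Most TG changes in the frontal cortex were smaller than this bound. Of 3534 called genes in males and 3257 in females, 370 and 495 rises and 44 and 65 falls reached 1.5-fold. The shares therefore rule out large sex differences only and do not show equal effects. In simulated data with these arrays' spread, a true difference of 1 log2 unit was found for 98% of genes in the frontal cortex and 96% in the hippocampus. A difference of 0.4 was found for 36% and 50%, so many smaller differences would be missed. The simulation changed genes drawn at random, with each gene's spread pooled over all groups. Plaque-associated genes can spread far more among TG hippocampus arrays. Cst7 had SD 0.88 in male and 2.46 in female TG arrays, mouse 7 included, against 0.19 and 0.12 in WT. For such genes these shares do not hold.

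The calls of the sexes overlapped. In the frontal cortex 2110 genes were called in the same direction in both, 1074 higher and 1036 lower, against 132.6 and 205.2 for independent lists, and 1 was called in opposite directions. In the hippocampus 118 were shared, 107 higher and 11 lower, against 2.76 and 0.418, and 0 were opposite. Fold changes of genes called in either sex had r = 0.944 in the frontal cortex and r = 0.925 in the hippocampus across genes, which are not independent replicates. Over all 17216 genes r was 0.879 in the frontal cortex and 0.658 in the hippocampus (0.593 without mouse 7). As groups, 4 lists passed camera for a sex difference in the frontal cortex and 9 in the hippocampus, among them glucocorticoid response (median 0.22 and 0.37) and heat shock and ER stress (median 0.22 and 0.17). None of them kept its call: the smallest adjusted p was 0.630 with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, passed 0.

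**Figure D3:**
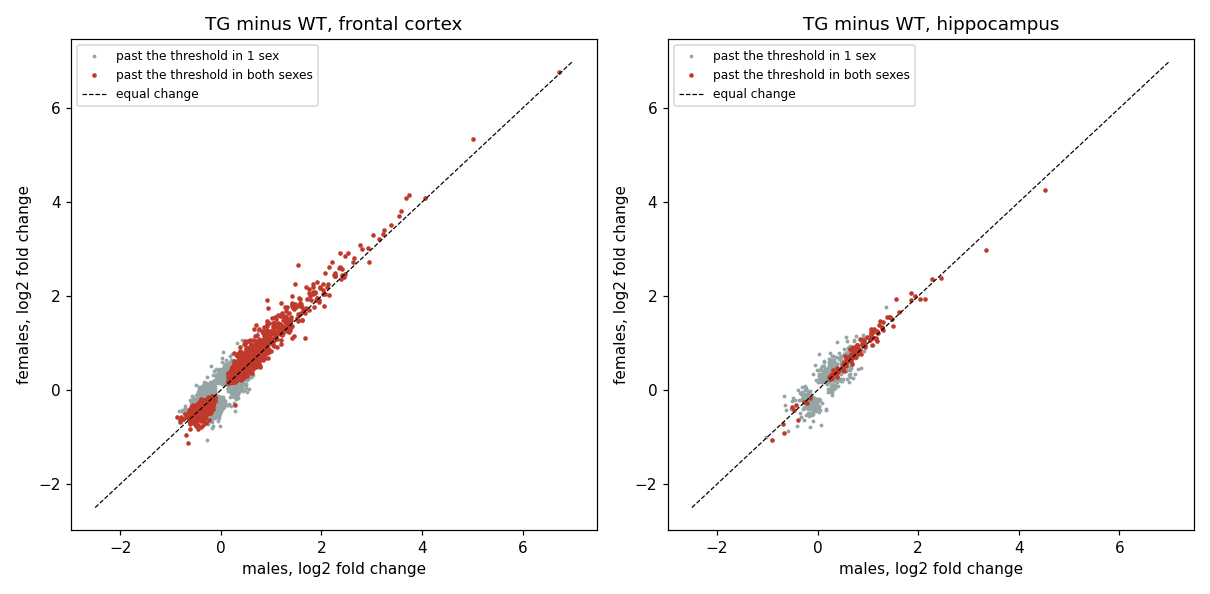
Log2 fold change of TG against WT in females (vertical) and males (horizontal) for genes called in either sex, with red points for genes called in both, grey points for genes called in 1 sex and a dashed line for equal change. Across these genes, chosen for a call, r was 0.944 over 4680 in the frontal cortex and 0.925 over 531 in the hippocampus, against 0.879 and 0.658 over all genes.

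Between WT females and males, genes of the sex chromosomes stood out. Xist, the RNA that silences an X chromosome, was higher in females by 6.47 log2 units (SE 0.07) in the frontal cortex (6 against 8 arrays) and by 6.80 (SE 0.06) in the hippocampus (7 against 8). The Y-linked genes Eif2s3y (-4.53, SE 0.12, and -4.54, SE 0.10), Uty and Kdm5d were lower. The X-linked genes Kdm6a (0.47, SE 0.07, and 0.69, SE 0.05) and Ddx3x (0.42, SE 0.07, and 0.44, SE 0.05), which escape silencing, were higher in females. In the frontal cortex the immediate early genes Fos (-1.13, SE 0.20) and Egr2 (-1.29, SE 0.23) and the transcription cofactor Sertad1 (-0.56, SE 0.10) were lower in females and Zfp40 was higher (0.56, SE 0.10). As a group, 5 of 23 immediate early genes were lower there (18 adjusted over the list alone), with a median of -0.45 and a call that held (adjusted p = 0.0173 with an estimated correlation). In the hippocampus their median was 0.07 with 0 past limma's threshold (0 adjusted over the list alone). In the hippocampus Kcnip4, which modulates potassium channels, was higher in females (0.41, SE 0.07), and the imprinted gene Nnat (-0.97, SE 0.17), Fhl1 (-0.31, SE 0.05) and Zfp58 (-0.47, SE 0.08) were lower. Among lists, 5 passed camera in the frontal cortex and 3 in the hippocampus, and that of immediate early genes alone kept its call.

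In all, 27 genes differed between WT females and males in the frontal cortex, 10 higher and 17 lower in females, and 175 in the hippocampus, 76 higher and 99 lower. With equal array medians the splits were 7 higher and 19 lower, and 96 higher and 69 lower. With array weights, all groups in the fit and the WT groups alone the counts came to 49, 73 and 12 in the frontal cortex and to 751, 295 and 325 in the hippocampus. The frontal count came to 55, 69 and 16 without male mice 38, 39 and 49 and to 14 without female mouse 5. The hippocampal count came to 273, 348, 90, 83, 72, 103, 65 and 79 without male mice 38, 39, 42, 47, 48, 49, 51 and 52. It came to 66, 91 and 86 without female WT mice 1, 3 and 5, and to 498 without the female TG array of mouse 4. The 10 named genes of each region kept their calls without any 1 array, but with the WT groups alone Zfp40, Egr2 and Sertad1 in the frontal cortex did not pass (adjusted p = 0.0515, 0.0662 and 0.0515).

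Whether the transgenes acted differently in the regions was tested as the hippocampal effect minus the frontal effect. In males Gfap differed by -2.37 (SE 0.33), the lipase Lpl by -1.54 (SE 0.19), the oxidase subunit Cyba by -1.79 (SE 0.31) and Sparc by -0.95 (SE 0.14). Each rose in the frontal cortex, with Gfap at 3.75 there against 1.38 in the hippocampus. In females Gfap differed by -2.59 (SE 0.36), Cebpd, a transcription factor of inflammation, by -1.58 (SE 0.25), the tetraspanin Cd9 by -1.52 (SE 0.28), Lpl by -1.39 (SE 0.21) and the checkpoint receptor Havcr2 by -1.07 (SE 0.20). Adcyap1, which fell in the frontal cortex, differed by 0.998 (SE 0.16). Gfap started higher in the WT hippocampus (6.81, SD 0.07, in males) than in the WT frontal cortex (4.35, SD 0.28). Genes of plaque-associated microglia had median differences of -0.70 in males and -0.93 in females, with 11 and 10 of 29 lower (24 and 24 adjusted over the list alone, and 1 higher in females). Among lists, 11 passed camera in males and 14 in females, and none kept its call over the arrays taken as independent (plaque-associated microglia: adjusted p = 0.0547 with an estimated correlation in each sex). With the mouse as a fixed replicate block, 26 list tests passed, 17 of them with an estimated correlation. That of plaque-associated microglia had adjusted p = 0.000134 in males and adjusted p = 0.000246 in females with an estimated correlation. The block also leaves out mice 3 and 7, so for the lists the effect of pairing was not separated from that of leaving them out.

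In all, the effect differed between regions for 285 genes in males, 101 with a higher and 184 with a lower value in the hippocampus, and for 174 in females, 35 and 139. With the mouse as a fixed replicate block, which leaves out mice 3 and 7, the counts came to 726 and 406. They came to 702 and 564 with array weights, and the male count came to 182 with the choroid plexus covariate. Without the array labelled female TG hippocampus mouse 7 the female count came to 64, and without that of mouse 4 the counts came to 520 and 793. Of the 224 genes called in the male hippocampus, 178 were called in the same direction in the male frontal cortex, against 15.8 and 5.28 higher and lower for independent lists. Of all 224, 161 had the smaller change in the hippocampus. The regions share mice, so these lists are not independent. Of the 425 in females, 320 were shared, against 23.2 and 16.3, and 299 of all 425 had the smaller change in the hippocampus. No gene was called in opposite directions in the regions.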

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

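The tests of the 3 patterns below were chosen after the results were seen, and what the other splits would show was written down after their counts were seen.

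The array labelled female TG hippocampus mouse 7 lies far below the other TG arrays for Thy1, at 10.92 against 11.90 to 12.32, and its choroid plexus list mean of 7.73 lies above the others of its group (3.61 to 4.41). An exchange with a wild-type array of the series is argued against, since 0 of the 29 wild-type arrays reach the lowest Thy1 of the 28 other TG arrays (11.90, against a wild-type maximum of 11.42). On a scale from the wild-type mean at 0 to the TG mean at 1, over 171 genes raised in the other female TG hippocampus arrays, its median position was 0.0664 (0.230 or more in those arrays and at most 0.0544 in wild-type arrays), so a wild-type sample under a transgenic label may account for it. A transgene that was silent in this mouse stays open, because there are 0 frontal cortex arrays of mouse 7.

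The TG effect was smaller in the hippocampus than in the frontal cortex. A larger spread between hippocampus arrays may account in part for the lower number of calls within the plaque-associated list, with a median ratio of residual SDs of 1.28. Over all genes the ratio was 0.952, so no larger spread was found to account for the lower total count. Nor does spread account for the lower rises, whose mean region difference over 14 mice was -0.87 (SE 0.06). Both ratios include the arrays of mice 4 and 7. Without them the ratio over all genes was 0.901, and that over the list was not computed. The array of mouse 7 is argued against as the source of the lower rises, since 14 of 14 TG mice with arrays of both regions had the smaller rise of the plaque-associated list in the hippocampus (exact two-sided sign test p = 0.000122, mean rises 1.17, SD 0.48, and 2.04, SD 0.31). Scaling is argued against by a mean region difference of -0.88 (SE 0.09, 8 males) with equal array medians, against -0.89 without. A biological difference between the regions, such as the extent or timing of amyloid, stays open and was not tested, and may add to these values of -0.88 and -0.89.

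Choroid plexus genes were higher in the male TG hippocampus. Uneven carry-over of choroid plexus may account for it: within groups the 15 genes went up and down together (median correlation of a gene with the mean of the others 0.974, and 0.967 in wild-type groups alone), and a list mean above 6 also occurred in 1 male and 1 female wild-type array. An effect of the transgenes on these genes cannot be told apart from it with 8 arrays a group: the list mean differed by 1.58 (exact two-sided permutation p = 0.0603), and in females without the array of mouse 7 by -0.24 (SE 0.36, exact permutation p = 0.664). Choroid plexus tissue as the origin of the microglial rise in males is argued against, since the plaque-associated list kept a median of 0.61 with the covariate, against 0.69 without. Cst7 was then at 4.91 (SE 0.64) and Trem2 at 2.05 (SE 0.37). The count of genes fell from 224 to 60 and the median standard error grew 1.11 times, but the cause of the lower count was not tested.

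Other samples far from the rest of their group, among 144 tested sets of values of which chance gives about 1 in 20, or 7.2, and 14 were found, were as follows. The frontal cortex array of male WT mouse 51 had Gfap at 4.99, Trem2 at 5.34 and Neurod6 at 8.01, and that of female WT mouse 1 had Gfap at 4.58. Trem2 was 5.59 in the female WT hippocampus of mouse 1, Xist 3.41 in the male WT hippocampus of mouse 48, Eif2s3y 7.60 in the male TG frontal cortex of mouse 44 and Lct 4.55 in that of mouse 41. The female TG hippocampus of mouse 4 had Neurod6 at 8.45 (others 9.54 or more) and a hippocampal field list mean of 5.31 (others 6.41 or more). The choroid plexus list mean was 7.27 in the male WT hippocampus of mouse 52 and 6.12 in the female WT hippocampus of mouse 5.

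Differences between groups of mice or regions were sought by the tests of the difference itself. The TG effect differed between regions for 285 genes and 11 lists in males and for 174 genes and 14 lists in females. With an estimated correlation 0 of these list tests passed in each sex over the arrays taken as independent. The named genes in males were Lpl (-1.54), Gfap (-2.37), Sparc (-0.95), Ppfia4 (-0.84), Cyba (-1.79), Dock11 (-0.78), Rpl26 (-0.48), Lancl2 (0.49), Capn3 (-0.99) and Washc2 (-0.38). In females they were Gfap (-2.59), Lpl (-1.39), Cebpd (-1.58), Golm1 (-0.996), Adcyap1 (0.998), Ppfia4 (-0.94), Ptprf (0.54), Cd9 (-1.52), Il6ra (-0.70) and Havcr2 (-1.07). Between the sexes 4 lists in the frontal cortex and 9 in the hippocampus passed camera's preset. None of them passed with an estimated correlation, and 77 and 49 of 100 splits gave as many, so no list is shown to differ. Among the 640 probe sets with no gene name, which enter only the alternative with every probe set, 122 and 108 passed in the frontal cortex of males and females and 6 and 18 in the hippocampus.

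In 8 of the 10 comparisons 1 of 100 splits, the real one, gave as many genes past the threshold. For the counts of TG against WT and of the region difference chance is made unlikely rather than excluded. With 100 splits the share could not fall below 1 of 100, and it was not adjusted for the 10 comparisons. For TG against WT the real counts were 3534, 3257, 224 and 425 (frontal cortex males and females, hippocampus males and females) and the highest other 747, 1425, 9 and 86. For WT females against males they were 27 and 175 (highest other 4 and 1) and for the region difference 285 and 174 in males and females (highest other 12 and 18). Calls of sex chromosome genes such as Xist and Eif2s3y were certain under the real sex labels. The splits of WT females against males therefore do not show whether the other genes exceed chance. For the sex difference of the TG effect, with 0 genes in each region, 100 of 100 splits gave as many, and the highest other splits gave 4 in the frontal cortex and 52 in the hippocampus.

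For lists at the preset correlation, adjusted over the 29 tests of a comparison, fewer than 5 of 100 splits gave as many in the male hippocampus alone (18 lists, 2 splits, highest other 18). Another split equalled that count. The limit of 5 splits was not adjusted for the number of counts compared, so chance is made unlikely rather than excluded where fewer gave as many. Chance is not made unlikely for TG against WT in the male frontal cortex (16, 5 splits, highest 17), the female frontal cortex (17, 15 splits, highest 20) and the female hippocampus (16, 14 splits, highest 18). Nor is it for the sex difference (4 and 9 lists, 77 and 49 splits, highest 14 and 17), WT females against males (5 and 3, 30 and 68 splits, highest 9 and 11) or the region difference (10 and 14, 20 and 11 splits, highest 14 and 17). With an estimated correlation fewer than 5 splits gave as many in all 4 TG comparisons: 10, 11, 11 and 8 lists in the order above, with 1, 2, 1 and 2 splits giving as many and highest others of 0, 11, 1 and 8. Another split thus equalled the real count in the female frontal cortex and the female hippocampus. Fewer than 5 also did so for WT females against males in the frontal cortex (1 list, 2 splits, highest 1) and the female region difference (1 list, 1 split, highest 0). In the other 4 cases 0 lists passed and 100 of 100 splits gave as many, the highest others being 6 and 9 for the sex differences, 1 for WT females against males in the hippocampus and 1 for the male region difference. The splits of the region difference take the arrays as independent. With the mouse as a replicate block, for which no splits were drawn, 26 region list tests passed, 17 of them with an estimated correlation.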

How the results depend on the processing

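The fits without the hippocampus arrays of mice 4 and 7 or the frontal cortex array of mouse 51, with the choroid plexus covariate and with list tests under the block were chosen after the data were seen, and the cause of each change below was not tested unless stated. Averaging probe sets of a gene changes nothing, since each gene has 1.

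The frontal cortex TG counts stayed within 1.5 times under each alternative; leaving out arrays gave 3031 to 3857 in males and 2372 to 3558 in females. In the hippocampus the male TG count of 224 came to 616 with array weights, 518 with the male arrays alone, 60 with the covariate, 467 without mice 4 and 7, and 94 to 431 on leaving out 1 array (lowest without male TG mouse 50, highest without female TG mouse 4). The female count of 425 came to 22 with the female arrays alone and 178 to 604 on leaving out 1 array (without female TG mice 11 and 8). The sex differences, 0 genes in each region with 1130 and 842 at an unadjusted p under 0.05 in limma, stayed at 0 on leaving out any 1 array, and 1 gene passed in the hippocampus with the covariate.

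WT females against males gave, in the frontal cortex, 49 with array weights, 73 with all groups in the fit, 12 with the WT groups alone and 14 to 69 on leaving out 1 array (without female mouse 5 and male mouse 39). In the hippocampus they gave 751, 295 and 325 in the same order, 91 without mice 3 and 7, 503 without mice 4 and 7, and 65 to 498 (without male WT mouse 51 and female TG mouse 4).

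The region differences of 285 in males and 174 in females came to 702 and 564 with array weights and to 541 and 665 without mice 4 and 7. They came to 726 and 406 with the mouse as a fixed replicate block, which leaves out mice 3 and 7. With the mouse as a random block they came to 535 and 366. The male count was 182 with the covariate and 359 to 520 without mouse 7 or mouse 4; the female count was 38 without mice 3 and 7 and 64 to 793 without mouse 7 or mouse 4. The block applies to no other comparison, since the other groups share no mouse within a region.

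List tests came, with an estimated correlation, from 67 to 37 for TG against WT, from 13 to 0 for the sex difference, from 8 to 1 for WT females against males and from 25 to 0 for the region difference. With fry the last 3 came to 0, 4 and 15. Under the fixed block, which leaves out mice 3 and 7, the region lists numbered 26, and 17 with an estimated correlation. Without mouse 7 the families gave 68, 15, 8 and 27. The sex chromosome list, with a median of 0.20 in WT females against males in the frontal cortex, turned from down in camera (not past the threshold) to up in fry (past it); it holds genes higher in each sex.

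Overlaps between the sexes fell from 2110 to 1121 and from 118 to 32 at a threshold of 0.01, a stricter limit by construction, and the hippocampal one came to 47 with the covariate and 183 without mice 4 and 7. Without mouse 51 the frontal overlap was 2238, and the hippocampal one was 125 to 168 without mouse 4 or mouse 7.

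Values of named genes kept their direction and side of the threshold in 5166 of 5452 cases, with 152 weaker, 134 stronger and 0 reversed, and on leaving out 1 array in 8100 of 8531, with 337 weaker and 94 stronger. List values did so in 1345 of 1508 cases, with 139 weaker, 23 stronger and 1 reversed, and without mouse 7 in 285 of 290. These counts include frontal cortex comparisons, whose list medians cannot change when a hippocampus array is left out. Of the named genes past the threshold, 76 of 93 and 80 of 97 held in every setting in the frontal cortex of males and females, but 23 of 46 and 5 of 58 in the hippocampus (33 and 43 on leaving out any 1 array). For WT females against males 7 of 10 held in the frontal cortex and 10 of 10 in the hippocampus. No detection calls or background values limit what can be said of dim genes: 25th percentiles of 3.26 to 3.38 lie 1 log2 unit above the lowest value, 2.28.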

Other observations

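The relations across mice below and the genotype differences of the clock score were chosen after their values or related values had been seen, the 8 further gene lists were written after the main results but before they were tested, and the tests of clock genes between the sexes were planned before their values were seen.

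Further gene groups moved in the frontal cortex. Chemokine genes rose in 9 of 14 in males and 10 of 14 in females, with 1 falling in each (10 and 11 higher adjusted over the list alone), at medians of 0.63 and 0.65. Cytosolic ribosomal protein genes rose in 4 and 5 of 7 (4 and 6 adjusted over the list alone; medians 0.27 and 0.50), and pattern recognition receptors in 6 and 7 of 13 (7 and 7 higher, and 1 lower in females, adjusted over the list alone). Voltage-gated potassium channel genes, which set the excitability of neurons, fell in 9 and 10 of 13 (12 and 11 adjusted over the list alone), with medians of -0.30 and -0.39. Over 80 tests of these lists the calls held in both sexes, the highest adjusted p being 0.0371 with an estimated correlation. The lists were chosen with the main results in view, so these calls describe the same data and are not independent support. Neuropeptide genes fell in 5 and 7 of 15 (5 and 9 adjusted over the list alone), and their calls were lost (adjusted p = 0.261 and adjusted p = 0.110 with an estimated correlation). Clock genes of the morning phase fell in 4 and 2 of 5 (5 and 3 adjusted over the list alone; medians -0.30 and -0.21), and their call was lost in males and not made in females (adjusted p = 0.0783 and adjusted p = 0.115 with an estimated correlation), while fry passed in both. Proliferation genes rose in 1 and 3 of 9 (0 and 3 adjusted over the list alone), and did not pass as a group in males or keep a call in females (adjusted p = 0.433 and adjusted p = 0.189 with an estimated correlation). In the hippocampus chemokine genes rose in 5 and 4 of 14, with 1 falling in females (7 and 9 higher adjusted over the list alone), with adjusted p = 0.0533 and adjusted p = 0.0783 with an estimated correlation. The other groups called in the frontal cortex had no call that held there either, with adjusted p = 0.139 and 0.104 for potassium channels, 0.370 and 0.110 for ribosomal proteins and 0.0981 and 0.102 for pattern recognition receptors with an estimated correlation. For ribosomal proteins in males no call was made (camera adjusted p = 0.0686 at the preset correlation).

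TG mice with a higher plaque-associated microglial score in the frontal cortex had a higher score in the hippocampus among the 6 females with both regions (Pearson r = 0.953, exact permutation p = 0.00972, adjusted 0.0292 over 6 relations; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted 0.05; r = 0.826 without the 2 mice farthest from the median). The highest hippocampal score was that of mouse 4, whose array has a low mean of hippocampal field markers (5.31), so the relation may in part reflect tissue content. Among 8 males the relation was weaker (r = 0.756, exact permutation p = 0.0300, adjusted 0.0600; rho = 0.690, exact permutation p = 0.0694, adjusted 0.139) and rests on 2 mice, with r = 0.308 without them. A mouse's amount of plaque may set the score in each region, to which values of 0.953 and 0.756 would correspond, but plaque was not measured here.

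Between Thy1 and the same score, the 8 male TG hippocampus arrays had r = 0.969 (exact permutation p = 0.000719, adjusted 0.00432; rho = 0.905, exact permutation p = 0.00456, adjusted 0.0274; r = 0.938 without the 2 arrays farthest from the median). In the same arrays the mean of the choroid plexus markers had r = 0.684 with Thy1 (exact permutation p = 0.0951, adjusted 0.112 over 2 relations; rho = 0.595, exact permutation p = 0.132, adjusted 0.243; r = 0.517 without 2 arrays). With the score it had r = 0.624 (exact permutation p = 0.112, adjusted 0.112; rho = 0.476, exact permutation p = 0.243, adjusted 0.243; r = 0.554 without 2 arrays). The partial correlation of Thy1 and the score given these markers was 0.951. The relation was not found in the male frontal cortex (8 arrays, r = 0.468, exact permutation p = 0.240, adjusted 0.360; rho = 0.333, exact permutation p = 0.428, adjusted 0.597; r = 0.765 without 2 arrays). It was not found in the female frontal cortex either (6 arrays, r = -0.155, exact permutation p = 0.790, adjusted 0.915; rho = -0.0857, exact permutation p = 0.919, adjusted 0.919; r = 0.879 without 2 arrays). In the female hippocampus without mouse 7 (6 arrays) r was 0.0618 (exact permutation p = 0.915, adjusted 0.915; rho = -0.371, exact permutation p = 0.497, adjusted 0.597; r = -0.988 without 2 arrays), so the relation held in 1 of 4 groups.

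The hypothesis that the sexes were sampled at different times of day was tested with clock genes in WT mice, as the mean of 8 evening-phase genes minus that of 5 morning-phase genes. The score was higher in females by 0.24 log2 units in the frontal cortex (0.25, SD 0.15, n = 6, against 0.01, SD 0.14, n = 8; exact two-sided permutation p = 0.0107) and by 0.32 in the hippocampus (0.21, SD 0.19, n = 7, against -0.11, SD 0.16, n = 8; exact two-sided permutation p = 0.00451). The regions share mice, so these p values are not independent. As lists, evening-phase and morning-phase genes had no call that held for WT females against males. With an estimated correlation camera gave adjusted p = 0.370 and 0.268 in the frontal cortex and 0.189 and 0.364 in the hippocampus, and fry passed neither list. The score also differed between genotypes in the frontal cortex of males, higher in TG by 0.28 (8 against 8 arrays, exact two-sided permutation p = 0.00311, adjusted 0.0124 over 4 tests). This came from the morning-phase genes, since 0 of 8 evening-phase genes passed in limma there (median -0.04, 0 adjusted over the list alone, camera adjusted p = 0.899). The TG difference was 0.20 in the female frontal cortex (6 against 6, exact permutation p = 0.0260, adjusted 0.0520), 0.15 in the male hippocampus (8 against 8, exact permutation p = 0.0977, adjusted 0.130) and 0.05 in the female hippocampus (7 against 7, exact permutation p = 0.555, adjusted 0.555). The score is therefore not particular to the sexes. A different time of sampling may lie behind part of the differences between WT females and males, and an effect of sex itself on clock genes stays open, since sampling times are not given in the sources used here.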
